A study of Homo sapiens with 6 samples.

How the data were processed

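RNA-seq was carried out on human aortic valve tissue from 2 groups, 3 stenotic valves and 3 sclerotic valves, with 1 library per sample. Aortic valve stenosis is the narrowing of the valve opening that follows fibrosis and calcification of the leaflets. Aortic valve sclerosis is the earlier thickening of the leaflets without obstruction of flow. Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, libraries were made from total RNA with the NuGEN Ovation RNA-Seq kit, sclerotic valves were obtained from heart transplant recipients, and patients were enrolled at valve surgery or at heart transplantation. Disease stage therefore cannot be separated from tissue source in this design. The labels list the samples separately but do not say of each that it came from a separate patient, so p-values measure the spread between these samples.

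The deposited files give 1 value for each of 16330 genes per sample. The values were read as FPKM, that is fragments mapped to a gene, scaled by its length and by the mapped fragments of the library, because the submitters' processing notes name Cufflinks. The file headers do not name a unit. Sums differed between samples, from 320852 to 1752380, whereas TPM values share 1 sum. Per the submitters' processing notes, the authors used STAR, SAMtools and Cufflinks 2.2.1 with the human genome build hg19. The versions of STAR and SAMtools, the annotation release and the strand setting are not given in the sources used here. All 16330 genes had a mean of at least 1 FPKM in the stenotic or the sclerotic group, and the lowest such mean was 1.00004, so the tables had been limited by group mean before deposit. A gene at low level in both groups was thus outside the comparison. No mitochondrially encoded gene was listed. The files hold no read counts. Sequencing depth is unknown, and no counting interval or detection floor was computed. An FPKM value is relative to the other transcripts of its library, so a few abundant small RNAs can affect the values of the remaining genes.

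In 2172 genes at least 1 library had a value of exactly 0. Some of these are genes that most cells use, such as DCTN3 and POLR2G in sclerotic replicate 1, so a 0 can be a failed estimate. Genes with such values are described as listed at 0, with the value of each library. Gene identifiers were matched without their version to a table of gene names. That table named 15784 of the 16330 genes, and 15851 were named by it or by the GENCODE 29 annotation. The annotation is on another build than the files, so it was used for names, gene classes and transcript lengths, and no coordinates are given. XIST and Y-linked genes were removed before any test, which left 16294 genes.

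Values were transformed as log2(FPKM + 1). Genes with at least 1 FPKM in at least 3 of the 6 libraries were tested, 13616 in all, of which 11813 were protein coding. Stenotic and sclerotic samples were compared with limma 3.58.1 in R 4.3.3, with an intensity trend in the prior variance, no covariate and no block, two-sided, and Benjamini-Hochberg adjustment at 0.05. All 6 samples entered the fit. Fold changes are stenotic over sclerotic on the log2(FPKM + 1) scale, which understates changes of genes at low level. A test of ranks in 3 against 3 samples cannot give an exact permutation p under 0.1. In simulated data with 200 changed genes among the 13616, limma recovered 1.1% of genes changed by a log2 fold of 1, 31.9% at 2, 67.9% at 3 and 88.5% at 4, with 3.55 false calls per simulation. The comparison can therefore miss most moderate changes. Genes were simulated independently and with the same spread in both groups, so these rates may not carry over to the real data.

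There were 38 gene lists fixed before the data were examined, covering mineralization, matrix, signalling, stress, lipid and cell type markers. Of these, 36 had at least 5 tested members. They were tested with camera of limma at the preset inter-gene correlation of 0.01, with camera at an estimated correlation, with camera on ranks, and with the rotation test fry. In simulated data camera at the preset correlation found 50 of 50 shifted lists and called 0 of 50 unshifted lists. Genes were simulated independently of each other, so this check does not cover lists whose genes vary together. The mitochondrially encoded genes had 0 tested members and the erythrocyte markers 3, so these lists were not tested. Camera asks whether a list stands apart from the other genes. The lists of aortic stenosis risk loci, heat shock, hypoxia-response and complement genes, like the other lists, are reported whatever their result.

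The genes named in the text were chosen by a rule fixed together with the lists. It took 12 genes per direction, first those past the threshold with the largest change and then those of smallest p, with no overlap between groups. Genes without a protein product were passed over, applied here as gene class. It added up to 4 members of each list with the smallest p, the 2 most abundant members of each cell type list, and 14 genes of valve disease. The small RNA genes, the immunoglobulin genes and the genes given in the account of single libraries lie outside this rule and were chosen after their values were seen. The list of glucocorticoid-response genes was written after the values of ZBTB16 and HIF3A were seen and before those of its other members were.

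Alternatives were a pseudocount of 0.1 or 0.5, no filter, a mean of at least 5 FPKM, rescaling by trimmed-mean factors, by the median or by quantiles, limma without the trend, sample quality weights, the replicate number as a block, and each library left out in turn. Alternatives chosen after seeing the data were protein-coding genes only, genes of at least 300 nt, genes above 0 in all 6 libraries, and protein-coding genes with trimmed-mean factors without sclerotic replicate 1. Random lists matched on expression, or on expression and transcript length, were drawn 10000 times. In a check on 40 random lists, all 40 were found after a shift of 0.5 and 2 without a shift. These 40 lists came from the same genes as the matched lists, so the check does not cover lists whose genes vary together. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.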

Results

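Gene expression was measured by RNA-seq of total RNA in 6 human aortic valve samples, 3 stenotic and 3 sclerotic, to compare the transcriptomes of the obstructed and the thickened but unobstructed valve. Single genes past the threshold were 6 small nucleolar RNAs and 1 long non-coding RNA, all higher in stenotic valves. Stenotic valves also had higher levels of fibrillar collagen, contractile, ribosomal protein and interferon-stimulated genes as lists. Adipocyte and lipid-handling lists were lower. These list calls were made with camera at a preset correlation, and 0 lists passed at an estimated correlation or with fry. Values are FPKM, given as mean ± SD over 3 samples unless each library is named. Listed FPKM summed to between 320852 and 1752380 per library, and sequencing depth is unknown.

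The libraries did not separate cleanly by disease. Sclerotic replicate 1 stood apart, with Spearman correlations of 0.584 to 0.676 to the other 5 libraries. Stenotic replicate 3 was closest to sclerotic replicate 2, with a correlation of 0.841, above its correlations of 0.780 and 0.760 with the other 2 stenotic libraries. Protein-coding genes took 12.7%, 10.2% and 29.1% of summed FPKM in stenotic replicates 1, 2 and 3, and 17.5%, 32.1% and 37.0% in sclerotic replicates 1, 2 and 3. FPKM is scaled by gene length, so these are not shares of reads. The 2 genes of highest FPKM in each library held 54.5%, 60.3% and 40.3% of the sum in stenotic replicates 1, 2 and 3. In sclerotic replicates 1, 2 and 3 they held 68.0%, 47.6% and 43.0%. Of 770680 FPKM in sclerotic replicate 1, small nuclear and small nucleolar RNA genes held 22438 and 23866. Genes of other classes, not protein coding, thus held most of that library's sum. Summed protein-coding FPKM was 154704, 178286 and 140937 in stenotic and 134505, 138387 and 118873 in sclerotic replicates 1, 2 and 3. It was thus highest in stenotic replicates 1 and 2, which had the smallest shares. Sclerotic replicate 1 listed 268 protein-coding genes at 0, against 43 to 101 in the other libraries.

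**Figure D1:**
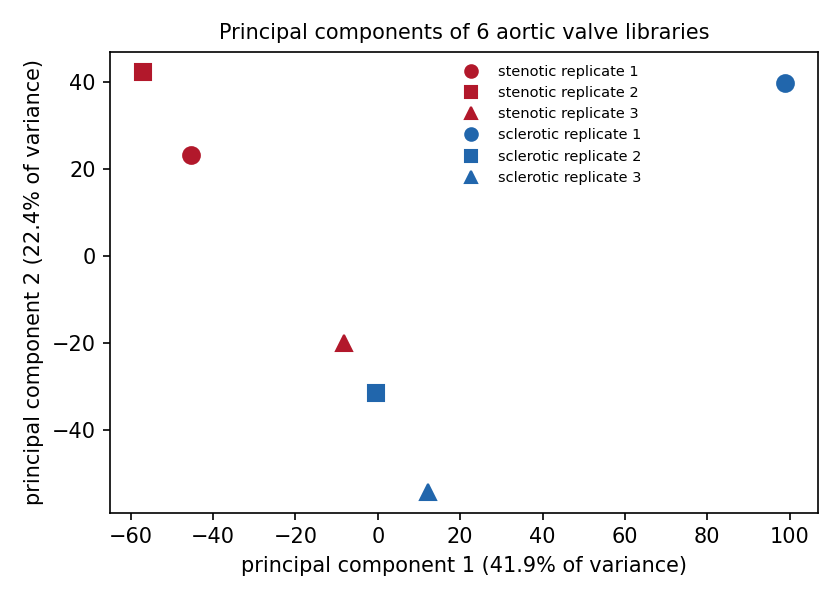
Principal components of log2(FPKM + 1) of the 13616 tested genes, with 1 point per library, red for stenotic and blue for sclerotic, and marker shape for replicate number. Component 1 (41.9% of variance) sets sclerotic replicate 1 at 99.0 apart from the others, and stenotic replicate 3 lies nearer to sclerotic replicates 2 and 3 than to the other 2 stenotic libraries.

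Small RNA genes were higher in stenotic valves. Small nucleolar RNAs guide the chemical modification of ribosomal and other RNAs. SNORA63D (ENSG00000201229.1) was at 1003, 1337 and 172 FPKM in stenotic replicates 1, 2 and 3 and was listed at 0 in all 3 sclerotic libraries. SNORA63 (ENSG00000200320.1) was at 709, 6578 and 157 FPKM, SNORA37 (ENSG00000207233.1) at 711, 140 and 115, SNORA70 (ENSG00000207165.1) at 136, 1542 and 66.6, and SNORA74A (ENSG00000200959.1) at 494, 366 and 20.2, each listed at 0 in the 3 sclerotic libraries. SNORA57 (ENSG00000206597.1) was at 276, 704 and 53.1 FPKM against 0, 0 and 3.62, and the long non-coding RNA ENSG00000270022.2 at 503, 610 and 62.2 against 0, 0.247 and 0.

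These 7 genes were the ones past an adjusted p of 0.05 among the 13616 tested with limma, all 7 higher in stenotic valves and 0 lower. Adjusted p ran from 3.67e-04 for SNORA63D to 0.0218 for SNORA74A. Apart from SNORA57 and ENSG00000270022.2, these genes had an SD of 0 in sclerotic valves. Identical values at 0, which can be failed estimates, thus enter these p-values. Without stenotic replicate 3, 29 genes were higher and 1 lower. Of the 52 small nucleolar and small nuclear RNA genes tested, 30 were higher and 0 lower at an unadjusted p under 0.05, with a median log2 fold change of 2.67. Small nuclear RNA genes summed to 255945, 222357 and 40578 FPKM in stenotic replicates 1, 2 and 3, and to 22438, 15653 and 10064 in sclerotic replicates 1, 2 and 3. Small nucleolar RNA genes summed to 79772, 89817 and 20199 FPKM in stenotic and 23866, 16600 and 9995 in sclerotic replicates 1, 2 and 3. The nucleolar sum of stenotic replicate 3 thus lay below that of sclerotic replicate 1. Small RNA families hold near-identical copies and many lie inside introns of other genes, so the share of reads given to each copy is uncertain. Among genes of at least 300 nt, 1 passed, and among genes above 0 in all 6 libraries, 0 passed.

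Across all tested genes at an unadjusted p under 0.05, 1009 were higher and 265 lower in stenotic valves, where 680.8 is the average by chance. That average gives no spread for genes that vary together across the 6 libraries. In either direction the real grouping gave 1274 genes. Other splits of the 6 samples into 3 and 3 gave 372 to 1005. The median log2 fold change of all tested genes was 0.22 rather than 0. After rescaling by trimmed-mean factors that median was 0.00 and the split was 515 higher and 524 lower, so the excess of higher genes goes with the scaling. Groups did not overlap for 1522 protein-coding genes that were higher and 345 that were lower, 15.8% of those tested, where chance gives 10% on average.

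No protein-coding gene passed. Of 11813 tested, 0 had an adjusted p under 0.05 with limma, and 816 were higher and 191 lower at an unadjusted p under 0.05. When only protein-coding genes were tested the lowest adjusted p was 0.0946. On the higher side SLN, which encodes sarcolipin, a regulator of the sarcoplasmic calcium pump, was at 6.23, 17.1 and 17.9 FPKM in stenotic and at 0, 0.773 and 0.138 in sclerotic replicates 1, 2 and 3 (log2 fold change 3.42, SE 0.50, limma adjusted p = 0.0567). TRO (trophinin, a cell adhesion protein; ENSG00000067445.16) was at 55.7 ± 36.1 against 4.21 ± 1.16 FPKM (n = 3 each), a log2 fold change of 3.25 with an adjusted p of 0.075 from limma. SMOC2, a secreted calcium-binding matrix protein, was at 8.67 ± 1.28 against 0.622 ± 0.365 FPKM. THBS2, which encodes the matricellular protein thrombospondin 2, was at 132 ± 42.6 against 25.5 ± 9.96 FPKM. MXRA5 had a log2 fold change of 2.90, ITGBL1 of 1.59, TENM4 of 2.26 and MAP3K7CL of 2.45. The linker histone gene H1-5 (log2 fold change 2.84), the core histone gene H2BC11 (2.53) and the keratin gene KRT18 (2.15) were each listed at 0 in sclerotic replicate 1. SLN passed without stenotic replicate 1 (adjusted p = 0.0362, range over its alternatives 0.0362 to 0.408), TRO without stenotic replicate 3 (0.0128, range 0.0128 to 0.413) and MXRA5 without sclerotic replicate 2 (0.0342, range 0.0342 to 0.659). With sample quality weights SMOC2 passed (limma adjusted p = 0.0415, range 0.0415 to 0.413), as did SLN (0.0372) and TRO (0.0186).

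On the lower side 0 genes passed the threshold. MGST1, a membrane-bound glutathione transferase, was at 2.05 ± 2.55 FPKM in stenotic and 22.5 ± 7.37 in sclerotic valves (n = 3 each), a log2 fold change of -3.25 (SE 0.58) with a limma adjusted p of 0.13. It passed without stenotic replicate 3 (0.0197, range over its alternatives 0.0197 to 0.582). HIF3A, a member of the hypoxia-inducible factor family, was at 0.0183, 0.0654 and 3.27 against 68.7, 8.54 and 23.4 FPKM in replicates 1, 2 and 3. The zinc finger transcription factor gene ZBTB16 was at 11.8 ± 3.81 against 97.1 ± 73.7 FPKM, and the metallothionein gene MT1X at 28.4 ± 3.32 against 120 ± 70.3. AKR1C1, an aldo-keto reductase, had a log2 fold change of -1.75, the haptoglobin gene HP of -2.33, FGFBP2 of -1.90, RNF112 of -1.91 and the adenylate cyclase gene ADCY4 of -1.88. HAND2, a transcription factor of heart and valve development, was at 12.5 ± 4.44 against 39.3 ± 7.6 FPKM.

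**Figure D2:**
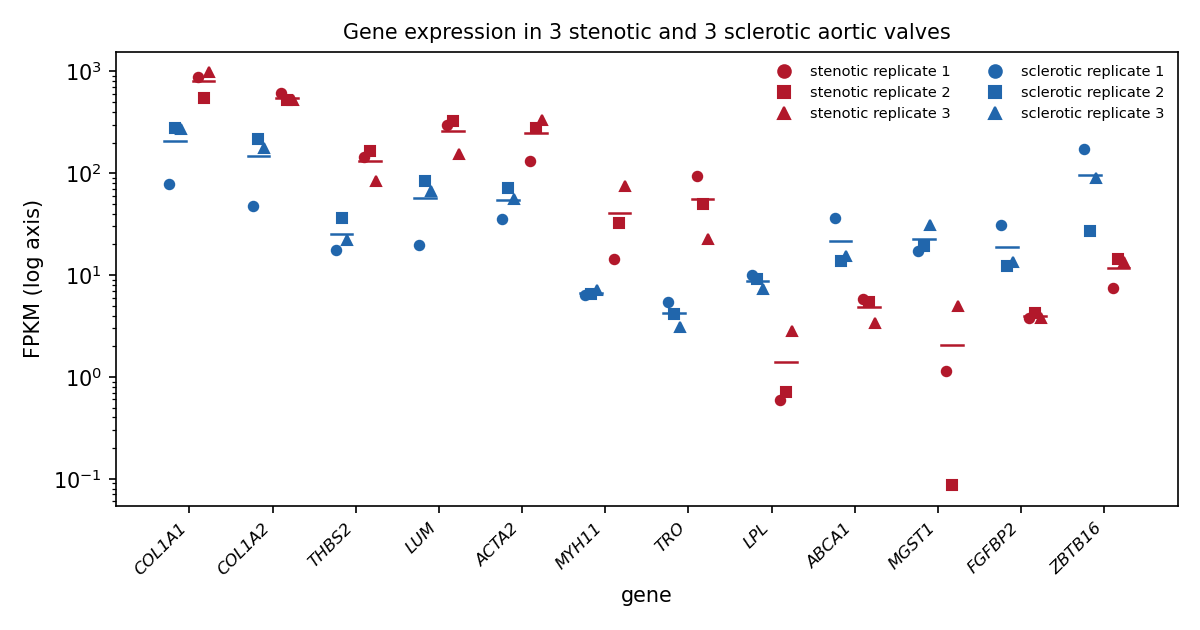
FPKM on a log axis of 12 named genes in 3 sclerotic (blue) and 3 stenotic (red) libraries, with marker shape for replicate number and a bar at each group mean. The groups do not overlap for any of the 12 genes, and none of them passed the threshold. Lack of overlap was required by the rule that named TRO, THBS2, ACTA2, MGST1, LPL, FGFBP2 and ZBTB16. The other genes shown were named for a small p within a list, so the lack of overlap reflects selection. COL1A1 lay at 208 ± 113 FPKM in sclerotic and 802 ± 226 in stenotic valves, and LPL at 8.81 ± 1.33 and 1.39 ± 1.27.

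Fibrillar collagen genes and the enzymes that cross-link them, the main load-bearing matrix of the valve, were higher in stenotic valves. COL1A1 (ENSG00000108821.9), which encodes the alpha-1 chain of type I collagen, was at 802 ± 226 FPKM in stenotic and 208 ± 113 in sclerotic valves (n = 3 each; log2 fold change 2.11, SE 0.56). COL1A2 was at 553 ± 46.8 against 148 ± 89 FPKM, COL8A1 at 33.1 ± 12.8 against 8.52 ± 5.17, and CTHRC1, a secreted protein of collagen-producing fibroblasts, at 24.1 ± 11.4 against 5.09 ± 2.06. Of 36 members tested, 16 were higher and 0 lower at an unadjusted p under 0.05. Adjusted over the list alone 13 passed, and adjusted over all genes 0 passed. The list's median log2 fold change lay 0.75 above that of all tested genes (camera adjusted p = 2.85e-07, and adjusted p = 0.779 with an estimated correlation). Sclerotic replicate 1 had the lowest level of the list, at -0.88 against -0.16 and -0.10 in the other 2 sclerotic libraries on the log2 scale. Fibroblast markers were lowest there too, at -0.84, against 0.22 and 0.02 in sclerotic replicates 2 and 3 and 0.37, 0.16 and 0.02 in stenotic replicates 1, 2 and 3. Without sclerotic replicate 1 the excess was 0.55 (camera adjusted p = 6.19e-06, range over the alternatives 4.83e-08 to 1.66e-05), and the log2 fold change of COL1A1 was 1.51.

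Smooth muscle and myofibroblast markers, the contractile genes of activated valve interstitial cells and of vessel walls, were higher in stenotic valves. ACTA2 (smooth muscle actin; ENSG00000107796.8) was at 248 ± 104 against 54.6 ± 18.3 FPKM (n = 3 each; log2 fold change 2.12, SE 0.45). MYH11, the smooth muscle myosin heavy chain, was at 40.4 ± 30.6 against 6.69 ± 0.351, CNN1 at 17.7 ± 5.75 against 4.0 ± 2.55 and the pericyte marker RGS5 at 19.9 ± 1.49 against 3.67 ± 3.02. The most abundant members, TAGLN and CALD1, had log2 fold changes of 1.52 and 0.87. Of 16 members tested, 9 were higher and 0 lower at an unadjusted p under 0.05, and 8 passed adjusted over the list alone. The list's median lay 1.03 above that of all tested genes (camera adjusted p = 8.85e-07, and adjusted p = 0.779 with an estimated correlation). Stenotic replicate 3 held its highest level, 1.12 on the log2 scale, against -0.08 and 0.44 in stenotic replicates 1 and 2. Heart muscle markers followed this list across libraries, at -0.04, 0.40 and 0.85 in stenotic and -0.39, -0.36 and -0.49 in sclerotic replicates 1, 2 and 3, beside -0.75, -0.31 and -0.46 for the smooth muscle list in sclerotic libraries. The heart muscle means rest on 5 tested of 27 markers. Among these SLN and MYOZ2 had log2 fold changes of 3.42 and 1.25, but ACTN2 and RYR2 of 0.35 and 0.17. For the smooth muscle list the camera adjusted p without stenotic replicate 3 was 0.00498, in a range of 9.98e-11 to 0.00498 over the alternatives.

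Ribosomal protein genes were higher by a small amount in many members. Of 68 tested, 65 had a log2 fold change above the median of all genes, 20 were higher and 0 lower at an unadjusted p under 0.05, and 0 passed adjusted over the list alone. RPS3A was at 129 ± 34.5 against 43.5 ± 11.3 FPKM (n = 3 each) and RPL22 at 85.3 ± 8.62 against 32.3 ± 16.6. RPS15A and RPL31 had log2 fold changes of 1.31 and 1.14. The list lay at 0.32, 0.41 and -0.05 on the log2 scale in stenotic replicates 1, 2 and 3, and at -0.36, -0.16 and -0.19 in sclerotic replicates 1, 2 and 3. The list's median lay 0.43 above that of all tested genes (camera adjusted p = 8.03e-10, and adjusted p = 0.95 with an estimated correlation). After quantile normalization the excess was 0.12 and the camera adjusted p 0.0562, in a range of 5.4e-13 to 0.0562 over the alternatives.

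Interferon-stimulated genes, the antiviral and inflammatory response genes induced by interferons, were higher in stenotic valves. GBP1 was at 11.5 ± 5.74 against 2.62 ± 1.02 FPKM, IFIT1 at 9.83 ± 6.22 against 1.42 ± 1.44 and IFIT3 at 6.23 ± 1.92 against 1.44 ± 1.16 (n = 3 each). ISG15 was at 14.7, 25.6 and 7.03 FPKM in stenotic and at 0, 7.08 and 3.71 in sclerotic replicates 1, 2 and 3. Of 25 members tested, 9 were higher and 0 lower at an unadjusted p under 0.05, and 0 passed adjusted over the list alone. The list's median lay 0.59 above that of all tested genes (camera adjusted p = 1.17e-04, and adjusted p = 0.779 with an estimated correlation). The list lay at 0.39, 0.63 and -0.10 on the log2 scale in stenotic and -0.36, -0.29 and -0.31 in sclerotic replicates 1, 2 and 3, and B and plasma cell markers at 1.22, 1.08 and -1.14 and at -0.42, -0.09 and -0.69. Without stenotic replicate 2 the excess was 0.34 (camera adjusted p = 0.00688, range over the alternatives 4.18e-06 to 0.00688).

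Antigen presentation genes were also higher as a list, with a median 0.36 above that of all tested genes (camera adjusted p = 0.0163, and adjusted p = 0.95 with an estimated correlation). B2M, the light chain of HLA class I, was at 771 ± 270 against 326 ± 54.4 FPKM, and HLA-C at 182 ± 40.4 against 90.2 ± 22.4 (n = 3 each). Of 25 members tested, 2 were higher at an unadjusted p under 0.05. The list lay at 0.65 and 0.54 on the log2 scale in stenotic replicates 1 and 2 but at -0.60 in stenotic replicate 3, within the sclerotic range. Leukocyte markers followed it in the stenotic libraries, with T and NK cell markers at 0.58, 0.54 and -0.75 and B and plasma cell markers at 1.22, 1.08 and -1.14 in replicates 1, 2 and 3. In sclerotic replicates 1, 2 and 3 antigen presentation genes lay at 0.28, -0.25 and -0.66 and T and NK cell markers at 1.03, -0.65 and -0.78. Camera adjusted p was 0.28 without stenotic replicate 1, 0.181 without stenotic replicate 2, 0.0794 without sclerotic replicate 2 and 0.249 without sclerotic replicate 3, and the call was lost in each, as it was after quantile normalization (0.0812). Over all alternatives it ranged from 3.63e-06 to 0.28, and the excess from 0.20 (without sclerotic replicate 3) to 0.70 (without stenotic replicate 3).

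Adipocyte markers were lower in stenotic valves. LPL (ENSG00000175445.10), the lipase that releases fatty acids from lipoproteins, was at 1.39 ± 1.27 against 8.81 ± 1.33 FPKM (n = 3 each; log2 fold change -2.15, SE 0.46). FABP4, a fatty acid carrier of adipocytes and macrophages, was at 0, 4.68 and 1.03 against 8.44, 10.01 and 3.31 FPKM in replicates 1, 2 and 3, and the lipid droplet gene PLIN1 had a log2 fold change of -1.41. Of 17 markers on the list, 9 were in the files, which hold only genes with a group mean of at least 1 FPKM, and 6 were tested. All 6 tested members lay below the median of all genes, and 3 were lower at an unadjusted p under 0.05. PLIN1 and PLIN4 stayed at or below 2.13 FPKM outside sclerotic replicate 2. LPL passed adjusted over the list alone. The list's median lay at -1.41 relative to that of all tested genes (camera adjusted p = 1.66e-05, and adjusted p = 0.779 with an estimated correlation). Without sclerotic replicate 2 it lay at -0.92 (camera adjusted p = 0.00458, range over the alternatives 2.97e-06 to 0.00458), and over the alternatives between -2.66 and -0.92. Stenotic replicate 3, at 0.01 on the log2 scale, was close to sclerotic replicate 3, at 0.14.

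Lipid uptake and lipoprotein genes were lower as a list. The cholesterol exporter gene ABCA1 was at 4.88 ± 1.28 against 21.7 ± 12.5 FPKM (n = 3 each; log2 fold change -1.84, SE 0.44), the lipid droplet gene PLIN2 at 6.04 ± 3.14 against 19.8 ± 9.31 and APOE at 87.6 ± 21.4 against 272 ± 172. Of 31 members tested, 6 were lower and 1 higher at an unadjusted p under 0.05. ABCA1 and LPL passed adjusted over the list alone. The list's median lay at -0.48 relative to that of all tested genes (camera adjusted p = 3.45e-04, and adjusted p = 0.779 with an estimated correlation). Sclerotic replicate 1 had the highest level of APOE, 470 FPKM, and without it the list's median lay at -0.11 relative to all genes. On the log2 scale that library was also highest, and stenotic replicate 3 lowest, both in this list (0.53 and -0.61) and in macrophage markers (0.63 and -0.76). Without stenotic replicate 2 it lay at -0.72 and without sclerotic replicate 3 at -0.73. The camera adjusted p was 0.0547 without stenotic replicate 3, in a range of 6.94e-06 to 0.0547 over the alternatives.

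**Figure D3:**
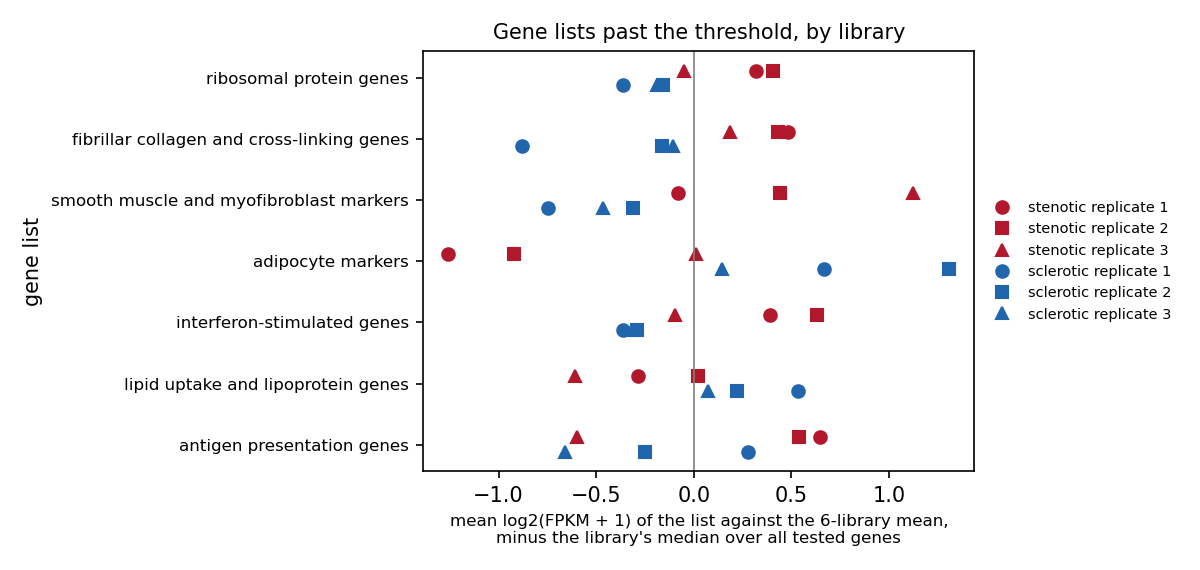
Mean log2(FPKM + 1) of each of the 7 gene lists past the threshold, relative to the 6-library mean and to the median over all tested genes of the same library, with 1 point per library, red for stenotic and blue for sclerotic, and marker shape for replicate number. Fibrillar collagen genes lay between 0.19 and 0.49 in stenotic and between -0.88 and -0.10 in sclerotic libraries, while antigen presentation genes overlapped between the groups.

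Each of these 7 lists was past the threshold with camera at the preset correlation, 5 higher and 2 lower. With an estimated correlation 0 lists passed, and with fry 0 passed (lowest adjusted p = 0.225), where fry tests whether a list moves one way without comparing it with other genes. The mixed form of fry, which counts changes in both directions, passed 2 lists that are not among the 7. These were heart muscle markers (mixed fry adjusted p = 0.0309) and cell cycle genes (0.0434).

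Genes of mineralization did not separate as lists. Osteogenic genes had a median 0.42 above that of all tested genes (camera adjusted p = 0.368), 0.10 without stenotic replicate 1, 0.23 without sclerotic replicate 1, 0.64 without stenotic replicate 3 and 0.66 without sclerotic replicate 2, and 2 of 18 tested members, SPARC and COL1A1, passed adjusted over the list alone. SPARC, a collagen-binding bone matrix protein, was at 623 ± 67.1 against 172 ± 89.7 FPKM (n = 3 each). RUNX2, the master transcription factor of osteoblasts, was at 4.64 ± 1.42 against 2.06 ± 0.455 and BMP2 at 3.03 ± 1.07 against 1.28 ± 0.619, with limma adjusted p of 0.556 and 0.586. The osteopontin gene SPP1 was at 338, 190 and 4.30 against 34.3, 69.7 and 33.1 FPKM in replicates 1, 2 and 3, and its fold change was negative without stenotic replicate 1. The alkaline phosphatase gene ALPL was at 11.3, 12.6 and 4.2 against 0.0805, 15.3 and 16.9 FPKM. Mineralization inhibitors had a camera adjusted p of 0.81. In that list SMAD6, an inhibitor of BMP signalling, was at 13.3 ± 4.23 against 29.04 ± 2.71 FPKM, and NT5E, which makes adenosine at the cell surface, at 15.3 ± 5.2 against 4.77 ± 3.63, neither past the threshold. The osteoclast markers had a camera adjusted p of 0.81 and the chondrocyte markers of 0.979. In the latter list ACAN, the large cartilage proteoglycan, had a log2 fold change of 2.13 and COL10A1 of 1.92.

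Other genes of valve disease did not pass. The calcification inhibitor gene MGP had a log2 fold change of 0.27 (SE 0.45), SOD3 of 0.26 (SE 0.56), CD44 of 0.20 (SE 0.45) and SOX9 of 0.22 (SE 0.51), each below 0 after rescaling by trimmed-mean factors. POSTN was at 0.84 (SE 0.80) and IL6 at 0.37 (SE 0.84), both below 0 without sclerotic replicate 1. NOTCH1 was at -0.09 (SE 0.39), the risk locus gene PALMD at -0.16 (SE 0.40) and ENPP2, which encodes autotaxin, at 1.11 (SE 0.52). The genes at aortic stenosis risk loci had a camera adjusted p of 0.81 as a list, with MECOM at 9.48 ± 7.04 against 28.4 ± 15.9 FPKM and FADS2 at 15.7 ± 6.91 against 6.65 ± 0.554 (n = 3 each), both without overlap between groups.

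Among other matrix lists, elastic fibre genes had a camera adjusted p of 0.0573, with FBN1 at 77.7 ± 7.53 against 36.2 ± 20.9 FPKM (n = 3 each). Proteoglycan and hyaluronan genes had a camera adjusted p of 0.109, with LUM at 259 ± 92.1 against 56.9 ± 33.5 FPKM. Sclerotic replicate 1 was lowest in both lists, at -0.88 and -1.07 on the log2 scale, and without it both had a camera adjusted p of 0.788. Over the alternatives adjusted p ranged from 0.00222 to 0.968 for elastic fibre genes, which passed without any 1 of stenotic replicates 1 and 2 and sclerotic replicates 2 and 3 (0.0124, 0.0312, 0.00222 and 0.0321). For proteoglycan genes it ranged from 0.00222 to 0.792, and they passed without sclerotic replicate 2 (0.00222) or 3 (0.0251). Matrix proteases and inhibitors had a camera adjusted p of 0.948, although MMP2, TIMP2 and the cysteine protease gene CTSK had log2 fold changes of 0.97, 1.03 and 1.16.

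Signalling lists did not pass. The camera adjusted p was 0.161 for TGF-beta and BMP pathway genes, 0.222 for WNT pathway genes, 0.554 for NOTCH pathway genes and 0.498 for renin-angiotensin and vasoactive genes. Without sclerotic replicate 2, WNT pathway genes passed (0.00465, range over the alternatives 0.00465 to 0.88), as did TGF-beta and BMP pathway genes (0.0319, range 0.0319 to 0.953). Within them TGFB3 was at 38.5 ± 6.64 against 11.5 ± 7.71 FPKM, the activin subunit gene INHBA at 15.3 ± 4.93 against 4.13 ± 2.59, the secreted WNT modulator gene SFRP4 at 58.3 ± 7.31 against 19.7 ± 15 and the NOTCH ligand gene JAG1 at 21.9 ± 2.61 against 6.94 ± 3.58 (n = 3 each). GUCY1A1, a subunit of the nitric oxide receptor, was at 34.4 ± 6.75 against 8.63 ± 4.71 FPKM and passed adjusted over the list alone.

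Stress and metabolic lists did not pass either. Immediate early genes had a camera adjusted p of 0.498, and FOS and FOSB differed within the stenotic group, FOS at 22.5, 383 and 289 FPKM and FOSB at 1.10, 76.9 and 121 in replicates 1, 2 and 3. Without stenotic replicate 1 the list passed (camera adjusted p = 4.76e-05, range over the alternatives 4.76e-05 to 0.924), as did FOSB (limma adjusted p = 0.0018, range 0.0018 to 0.87) and FOS (0.0277, range 0.0277 to 0.87). Heat shock genes had a camera adjusted p of 0.554, hypoxia-response genes 0.847, nuclear oxidative phosphorylation genes 0.0692, antioxidant and oxidant enzyme genes 0.985, complement genes 0.81, inflammatory cytokine and adhesion genes 0.612 and cell cycle genes 0.376. Oxidative phosphorylation genes passed without stenotic replicate 3 (0.00188) or sclerotic replicate 3 (0.0193), in a range of 0.00188 to 0.737. GPX3, a secreted glutathione peroxidase, was at 66.5 ± 17.03 against 200.5 ± 87.1 FPKM (n = 3 each).

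Markers of other cell types were measured beside these genes. Macrophage markers went both ways, with a camera adjusted p of 0.849. CSF1R was at 41.7, 56.7 and 13.1 against 9.36, 14.3 and 6.09 FPKM in replicates 1, 2 and 3, and C1QA at 109, 146 and 46.3 against 53.4, 42.4 and 19.2. The scavenger receptor gene MARCO was at 3.00 ± 1.64 against 13.9 ± 7.18 (n = 3 each), and CD68 and CD163 reached 249 and 246 FPKM in sclerotic replicate 1. The camera adjusted p was 0.612 for T and NK cell markers, 0.376 for B and plasma cell markers, 0.644 for mast cell markers, 0.828 for neutrophil markers, 0.644 for Schwann cell markers, 0.222 for fibroblast markers and 0.734 for endothelial markers. For macrophage, mast cell, neutrophil, Schwann cell, endothelial and chondrocyte markers, complement genes and antioxidant genes the test pointed lower although the list's median log2 fold change was above 0. Endothelial markers lay at -1.29 on the log2 scale in sclerotic replicate 1, against 0.56 and 0.79 in the other 2 sclerotic libraries. Without sclerotic replicate 1 they were lower in stenotic valves (camera adjusted p = 6.19e-06, range over the alternatives 6.19e-06 to 0.99, excess -0.86), and T and NK cell markers were higher (0.00509, range 1.87e-04 to 0.977). Without stenotic replicate 3 B and plasma cell markers were higher (0.0185, range 0.0185 to 0.735), and without stenotic replicate 2 neutrophil markers were lower (0.0328, range 0.0328 to 0.968). Heart muscle markers had 5 tested members and a camera adjusted p of 0.0993, and passed without stenotic replicate 1 (0.0124, range 0.0124 to 0.776). SLN and MYOZ2 passed adjusted over that list alone, while ACTN2 and RYR2 had log2 fold changes of 0.35 and 0.17.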

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

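The alternatives with protein-coding genes only, genes of at least 300 nt, genes above 0 in all 6 libraries, and protein-coding genes with trimmed-mean factors in 5 libraries were chosen after seeing the data. The alternatives listed for read counts did not apply to FPKM. Against 7 genes higher and 0 lower, both pseudocounts, no filter, a mean of at least 5 FPKM, every rescaling and limma without the trend gave 6 to 9 higher and 0 lower. All of the 7 genes were shared in each, except 6 of them at a pseudocount of 0.1. Sample quality weights gave 15 higher and 2 lower, and adjusting over each list alone gave 29 higher and 2 lower. The higher count was 0 with protein-coding genes only, 1 with genes of at least 300 nt, 0 with genes above 0 in all 6 libraries and 0 with protein-coding genes, trimmed-mean factors and 5 libraries, settings that leave 0 or 1 of the 7 genes to test. Leaving out 1 library gave 5 (without stenotic replicate 2) to 29 (without stenotic replicate 3) higher and 0 to 1 lower, with 5 to 7 of the 7 genes shared.

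Of the gene lists, 5 were higher and 2 lower. At a mean of at least 5 FPKM 1 was lower, and after quantile normalization 3 were higher. Camera on ranks gave 7 higher and 2 lower. With an estimated correlation and with fry 0 passed, 0 higher and 0 lower. Without 1 library each, 5 to 8 lists were higher and 1 to 3 lower. Collagen, smooth muscle and interferon lists passed in all 20 alternatives fitted and adipocyte markers in all 19 that could test them, ribosomal protein and lipid lists in 19 and antigen presentation in 15. Other than by the genes or samples that a setting removes, the cause was not tested.

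Of 3510 values of 179 named genes, 3495 kept their direction or changed sign with neither value at an unadjusted p under 0.05 (75 such changes), and kept their side of the threshold. Another 13 passed the threshold, among them SLN, TRO and MGST1. Protein-coding genes with trimmed-mean factors in 5 libraries turned the log2 fold change of ALPL to -1.10, and the excess of the list median to -0.0588 for elastic fibre and -0.22 for proteoglycan genes. It moved that of macrophage markers from 0.0062 to 0.21, with the test pointing higher instead of lower. Without 1 library each, S100A8 ranged from -1.21 to 1.11, proteoglycan genes from -0.18 to 0.52 and macrophage markers from -0.23 to 0.25.

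Same-numbered samples did not deviate together (correlations of -0.01, 0.04 and -0.02), so the numbers were not taken to pair samples. With the replicate number as a block 7 genes were higher, 6 of them shared, and 0 lower. Depth is unknown, so its part in these limits was not assessed.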

Other observations

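Antibody genes differed between libraries more than between groups. Variable-region genes of immunoglobulins, 61 of which were listed, summed to 779 and 573 FPKM in stenotic replicates 1 and 2, with 54 and 46 of them at 1 FPKM or more. In stenotic replicate 3 they summed to 2.36 FPKM, and in sclerotic replicates 1, 2 and 3 to 11.2, 113 and 3.06. JCHAIN, the joining chain of secreted IgA and IgM, followed with 71.6 and 61.6 FPKM in stenotic replicates 1 and 2, 0.172 in stenotic replicate 3 and 10.2 in sclerotic replicate 2. The constant-region gene IGKC was at 870 and 473 FPKM in stenotic replicates 1 and 2 and at 0.81 to 12.4 in the other 4 libraries. HBB, the beta chain of hemoglobin, was at 55.2 and 284 FPKM in stenotic replicates 1 and 2, 3.41 in stenotic replicate 3 and 0.666 to 2.95 in sclerotic libraries.

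Sclerotic replicate 1 combined high ferritin transcripts with a low level of COL1A1. FTL, the light chain of ferritin, was at 2008 FPKM there, against 556 to 1026 in the other 5 libraries, FTH1, the heavy chain, was at 1031 FPKM against 291 to 707, and COL1A1 was at 77.6 against 269 or more. Pseudogenes of mitochondrial genes summed to 1841 FPKM in that library and to 496 to 850 in the others.

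The test of the small RNA genes with each library left out was chosen after the result was seen. It replaced an undecided comparison of stenotic replicate 3 with the other 2 stenotic libraries. Also chosen after the result was seen were the test of 36 glucocorticoid-response genes and the splits of each pattern. So were the tests of the glucocorticoid-response genes with an estimated correlation and with fry. Sclerotic valves came from heart transplant recipients, so disease stage and tissue source are open as explanations of each pattern below and were not tested apart. Of the 10 splits of the 6 samples into 3 and 3, 1, the real one, gave 7 genes, and the highest other gave 3. For gene lists 8 splits gave 7 or more, and the highest other gave 16, with stenotic replicates 1 and 2 and sclerotic replicate 2 on 1 side. Too few splits exist for a share under 0.05. That split has more than the real count, so the number of lists past the threshold is not particular to disease group. Whether a structure of the samples other than disease group gives these counts was not tested.

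Small nucleolar and nuclear RNA genes were higher in stenotic valves, with a median 2.45 above that of all tested genes (95% bootstrap interval 1.90 to 3.41). The bootstrap drew genes and not samples, here and for the interval below. It treats genes as independent and holds no spread between the samples. The 64 tested genes of other classes under 300 nt had a median 0.20 above that of all genes (interval -0.24 to 0.51). This argues against a shift shared by all genes under 300 nt. The 64 genes were not matched to the small RNA genes on length or expression. Whether short length accounts for the pattern therefore cannot be settled by them. With each library left out in turn the lowest excess was 0.92 of that with all 6 samples (2.26, without stenotic replicate 1), which argues against 1 library rich in small RNA as the source but says nothing on 2, and small nuclear RNA sums of 255945 and 222357 FPKM in stenotic replicates 1 and 2 against 40578 in stenotic replicate 3 leave that open. A split with stenotic replicates 1 and 2 and sclerotic replicate 1 on 1 side gave an excess of 2.53, above the real one, so RNA extraction or library preparation may account for part of the pattern and was not tested.

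Ribosomal protein genes were higher as a list by 0.43 over all genes. Lists of other protein-coding genes matched on transcript length and expression had a median log2 fold change of 0.37 (95% of lists 0.21 to 0.50), above the 0.22 of all genes but below the 0.65 of the ribosomal protein genes, which 0 of 10000 lists reached (share 1e-04, the smallest they can give, with correlation between genes ignored). Length and expression therefore go with part of the excess. The matching was by bins of length and expression and ignored correlation, so it cannot settle whether they account for the rest. Without sclerotic replicate 1 the excess was 0.98 of its value with all 6 samples, which argues against that library as its source. The list lay at 0.32 and 0.41 on the log2 scale in stenotic replicates 1 and 2, the libraries of high small nuclear RNA, and at -0.05 in stenotic replicate 3. Splits with stenotic replicates 1 and 2 and sclerotic replicate 1, 2 or 3 on 1 side gave excesses of 0.24, 0.35 and 0.35. The real excess of 0.43 was the largest of the splits. What sets stenotic replicates 1 and 2 apart stays open. Quantile normalization left an excess of 0.12, so a difference in the shape of the libraries' distributions stays a candidate explanation.

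A lower level of glucocorticoid-response genes in stenotic valves was a hypothesis raised by ZBTB16 and HIF3A and tested on 39 other listed genes. Their median log2 fold change was -0.45, lower than in each of 10000 protein-coding lists matched on expression (share 1e-04, the smallest they can give). Such lists ignore correlation between genes. For the 39 genes p was 0.10 for camera at an estimated correlation and 0.20 for fry, so glucocorticoid exposure of the sclerotic valves stays open. Of the 39 genes 32 lay below the median of all genes, 5 were lower and 0 higher at an unadjusted p under 0.05, and 3 (PDK4, MT1X and GPX3) passed adjusted over the list alone, while the 36 without MT1X, GPX3 and ANGPTL4, which the report's naming rule also picked, had a median of -0.37 (share 1e-04). Without sclerotic replicate 1 the median was -0.42, which argues against that library alone, yet FKBP5 was at 58.5, 5.76 and 45.6 FPKM in sclerotic replicates 1, 2 and 3 and at 9.40 to 10.6 in stenotic libraries. A split with sclerotic replicate 2 on the side of stenotic replicates 1 and 3 gave an excess of -0.66 against the real -0.67, so sclerotic replicates 1 and 3 may carry much of it, and 5 of the 39 genes stand on other lists tested here.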
